A study of Homo sapiens with 11 samples.

How the data were processed

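Chromatin immunoprecipitation and sequencing (ChIP-seq) was done in MDA-MB-231 cells, a human triple-negative breast cancer line, with normal mdig protein (WT) and in cells in which mdig was removed (KO). Per the labels' protocols both kinds of cells came out of CRISPR-Cas9 work, and the KO cells made no mdig protein. Mdig is also called MINA53 or RIOX2, and the antibody against it is named MINA in the labels. Each of 5 antibodies (H3K4me3, H3K9me3, H3K36me3, H4K20me3 and MINA) was used on 1 WT and 1 KO chromatin sample, which gave 10 ChIP libraries. The remaining library of the series is input DNA, labelled with the cell line and no genotype, and it was not used here.

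The submitters' processing notes name BWA for the alignment, SICER version 1.1 for calling enriched intervals and the genome build hg19. The deposited file holds 1 interval list per ChIP library and 1 merged list of 92233 regions. At the 200-bp resolution of the file the merged list equals the union of the 10 lists, and it was not used further. Each interval has a chromosome, a start and an end and carries no height, fold, score or p-value. Every start and end lies on a 200-bp grid and neighbours in a list lie at least 800 bp apart. The window, gap and false discovery settings, any scaling to a common depth and the use of the input are not given in the sources used here. The read depth of the libraries is unknown, so no interval or detection floor that depends on depth is given. A list called with more reads or better enrichment holds more and wider intervals, and a ratio of list lengths cannot separate that from a change in the mark.

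The lists were compared on 200-bp windows with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, on chromosomes 1 to 22 and X. For each library the number of intervals, the covered length in Mb and the widths were computed, and for each antibody the KO over WT ratio of both. An interval counted as found in the other list when at least 1 bp overlapped. Counts of such intervals from bedtools 2.31.1 were the same in all 10 directions. Shares of intervals were given beside the mean and range expected from 100 circular shifts of one list along each chromosome, which keep the lengths and spacing of its intervals. The 95% Wilson confidence interval of a share reached at most 1.09 percentage points to either side in the comparisons between lists of WT and KO and between antibodies. These intervals cover counting error only. With 1 library per antibody and genotype there are no replicates, no test was run, and no p-value is given.

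Before the data were examined, the rule for naming regions was fixed as the 5 widest intervals found in only 1 genotype, the 3 chromosomes with the highest and the 3 with the lowest KO over WT ratio, and chromosome X. Intervals chosen by score were part of that rule and could not be named, since the lists hold no scores. Coordinates are 1-based on hg19. An annotation of hg19 was not used here, and the gene table at hand is for GRCh38.p14, so no gene was assigned to an interval. The planned counts of promoters and gene bodies, the fixed gene lists and the readout of RIOX2 itself were therefore not done.

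After the profile along the genome had been seen, stretches of chromosomes with a higher KO over WT ratio were cut from H3K4me3 alone. The log2 ratio of KO to WT covered length (1 kb added to each) in bins of 2 Mb was split into 2 states along each chromosome by a hidden Markov model with a chance of 0.001 for a change of state between neighbouring bins. Bins with less than 20 kb of H3K4me3 in WT and KO together took the state of their neighbours. The upper state is called raised stretches below. Tested on simulated data for the 1529 bins of the H3K4me3 comparison, the model found 90.2% of raised bins at a simulated ratio of 1.3 and called 1.57% of the others. At a simulated ratio of 1.1 it found 51.0%. With no raised bin in the simulation it called none. The simulated noise was independent between bins, so false calls from variation shared by neighbouring bins were not tested. Shares of shared intervals made in simulated lists were recovered exactly. Those lists held exact copies of WT intervals, so this checks the counting only.

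The alternatives fixed before the data were examined were to merge intervals within 5 kb, to add chromosome Y, to use autosomes only, to ask for 50% of the shorter or of both intervals in an overlap, to place intervals at random in place of circular shifts, and to compare interval numbers in place of lengths. Alternatives chosen after seeing the data were to leave out the raised stretches, to keep only intervals of at least 2 kb, and to cut the stretches with bins of 1 Mb or 5 Mb or from H3K36me3.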

Results

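The data comprised interval lists of enriched chromatin from 10 ChIP-seq libraries of MDA-MB-231 cells. They covered 4 histone marks and the mdig protein itself (antibody MINA) in WT cells and in cells lacking mdig (KO), with 1 library per antibody and genotype. Mdig is an oxygenase with a JmjC domain. H3K4me3 marks active promoters, H3K36me3 lies over the bodies of transcribed genes, and H3K9me3 and H4K20me3 mark silent heterochromatin. The lists held between 7859 intervals for MINA in KO and 53375 intervals for H3K9me3 in KO on chromosomes 1 to 22 and X. There were no replicates and the depth of the libraries is unknown, so the values below describe these libraries and were not tested.

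The MINA libraries addressed where mdig lies on chromatin, with the KO cells as the control for the antibody. The WT list held 16353 intervals over 119.6 Mb and the KO list 7859 intervals over 35.7 Mb, which is 0.298 of the WT length. Of the WT intervals 38.8% overlapped a KO interval, beside 3.93% expected from shifted lists (range 3.29% to 4.81%). Of the KO intervals 83.1% overlapped a WT interval, beside 8.09% expected (6.93% to 9.76%). Intervals that paired one to one were narrower in KO, with a median KO over WT width ratio of 0.778, which was 0.70 outside the raised stretches described further on and 1.09 inside them. The widest WT-only interval spanned 68.6 kb on chromosome 17 from 18860001 to 18928600 and overlapped H3K4me3, H3K36me3 and H3K9me3 intervals of both genotypes. The next 4 spanned 58.2 to 63.4 kb on chromosomes 15, 11, 10 and 17. The widest KO-only interval spanned 34.6 kb on chromosome 6 from 41642601 to 41677200, where no other list held an interval, and the next lay beside it from 41596801 to 41630400. The other 3, of 19.4 to 21.8 kb, lay on chromosomes 15, 20 and 5. The KO list thus gives the signal that the antibody returned in cells that per the labels made no mdig, and 6353 of the WT intervals were not distinguished from it by this comparison.

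For H3K4me3 the question was whether active promoters changed their mark without mdig. The 2 lists were close in number and position. WT held 19210 intervals over 120.7 Mb and KO 17825 intervals over 101.9 Mb, a covered length of 0.844 of WT. In KO 85.1% of the WT intervals were found (7.74% expected, range 7.25% to 8.52%) and 94.1% of the KO intervals were found in WT (8.45% expected, 7.60% to 9.17%). The shorter length went with narrower intervals. Of 15690 one-to-one pairs 65.6% were narrower in KO and 27.4% were wider. Outside the raised stretches described further on 72.5% were narrower and inside them 40.6%, a difference that follows in part from their definition by the H3K4me3 covered length. The 2854 WT-only intervals were small, with a median width of 2.0 kb against 6.0 kb for the kept ones. The widest WT-only interval, of 15.6 kb, lay on chromosome 20 from 23127001 to 23142600 and overlapped WT MINA and H4K20me3. The next 4, of 13.4 to 14.6 kb, lay on chromosomes 7, 6 and 17 over H3K36me3 and WT MINA intervals. The widest KO-only interval, of 11.6 kb, lay on chromosome 9 from 130301601 to 130313200, and the next 4, of 9.2 to 10.2 kb, on chromosomes 6, 10 and 5.

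H3K36me3, the mark of transcribed gene bodies, covered almost the same length in both genotypes. WT held 17507 intervals over 327.9 Mb and KO 17800 intervals over 328.8 Mb, a ratio of 1.00. Both lists shared 284.7 Mb, while 43.2 Mb were found in WT only and 44.2 Mb in KO only. The shares of intervals found in the other list were 85.5% in both directions, beside 17.1% (15.5% to 18.2%) and 16.9% (15.7% to 18.0%) expected. The widest WT-only intervals lay on chromosome 1, with 70.6 kb from 156195201 to 156265800, 65.0 kb from 224867001 to 224932000 and 49.6 kb from 234070801 to 234120400, and then on chromosomes 19 and 16. The widest KO-only interval spanned 86.6 kb on chromosome 9 from 137652601 to 137739200. The next, of 78.8 kb, lay on chromosome 3 from 38612001 to 38690800, and the other 3, of 62.0 to 68.6 kb, on chromosomes 6 and 7. The ratio was so close to 1 that its direction turned without chromosome X. Outside the raised stretches described below, KO covered 0.945 of the WT length.

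For H3K9me3, the mark of constitutive heterochromatin, much of the covered length differed in position. WT held 45805 intervals over 254.7 Mb and KO 53375 intervals over 305.7 Mb, 1.20 times the WT length. Only 155.4 Mb were common to both lists, 99.4 Mb were found in WT only and 150.3 Mb in KO only. Thus 39.0% of the WT length was absent from the KO list and 49.2% of the KO length was absent from the WT list. Of the WT intervals 68.6% were found in KO (15.7% expected, 13.2% to 17.7%), and 52.8% of the KO intervals in WT (13.9% expected, 12.1% to 16.0%). The count of intervals was 1.17 times that of WT, but 0.771 of it once intervals within 5 kb were merged, so that the merged KO intervals were fewer than the merged WT ones. The widest WT-only interval spanned 73.4 kb on chromosome 14 from 95155801 to 95229200. A neighbouring pair lay on chromosome 12 from 115119201 to 115170600 and from 115171401 to 115213400, and the other intervals lay on chromosomes 7 and 10. Of these 5, 4 overlapped H4K20me3 intervals of KO cells. The 5 widest KO-only intervals, of 44.0 to 55.2 kb, lay on chromosomes 5, 14 and X, the widest on chromosome 5 from 154936201 to 154991400, and all 5 overlapped H4K20me3 intervals of KO cells. All 5 lay inside the raised stretches described further on.

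Of the 5 antibodies H4K20me3 had the smallest part of its covered length in common between the genotypes (Jaccard index 0.165). WT held 8539 intervals over 67.2 Mb and KO 25318 intervals over 149.6 Mb, 2.23 times the WT length. The lists had 30.7 Mb in common, 36.5 Mb were found in WT only and 118.9 Mb in KO only. In KO 55.4% of the WT intervals were found (10.4% to 13.3% in shifted lists), and 19.6% of the KO intervals were found in WT (4.43% expected, 3.93% to 5.02%). The widest WT-only intervals were 77.2 kb on chromosome 11 from 76851401 to 76928600 and 58.0 kb on chromosome 7 from 100340801 to 100398800, both over H3K9me3, H3K4me3 and MINA intervals of WT cells. The next 3, of 49.4 to 56.0 kb, lay on chromosomes 12, 17 and 11. Of the 5 widest KO-only intervals 3 lay on chromosome 6, with 145.0 kb from 41355801 to 41500800, 135.6 kb from 39751601 to 39887200 and the smallest of the 5 from 37662601 to 37742600. Those 3 on chromosome 6 overlapped H3K4me3 intervals of both genotypes. The others were 93.2 kb on chromosome 20 from 40694001 to 40787200 and 80.2 kb on chromosome 5 from 176098801 to 176179000.

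**Figure D1:**
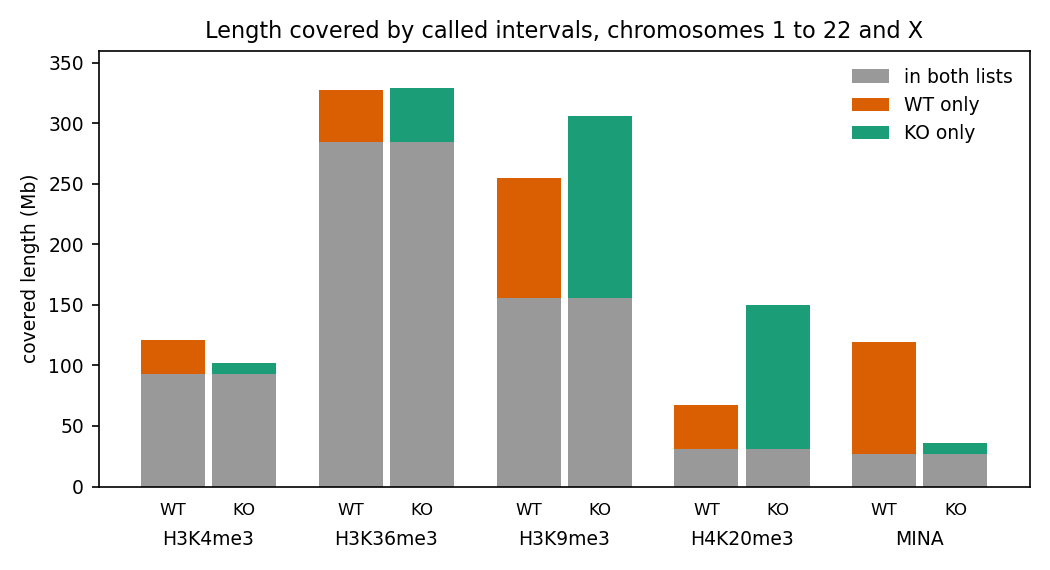
Length in Mb covered by called intervals (vertical axis) for each antibody in WT and KO cells, 1 library per bar, with the part in both lists in grey and the part in 1 genotype only in colour. The MINA bar shrinks from 119.6 Mb in WT to 35.7 Mb in KO, and the H4K20me3 bar grows from 67.2 to 149.6 Mb, of which 118.9 Mb are in KO only.

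The next comparison asked which marks lay where the MINA antibody gave signal. In WT 71.7% of the MINA intervals overlapped H3K4me3 (10.3% expected, 9.33% to 11.5%) and 7353 of the 16353 overlapped H3K36me3 (16.0% of them expected, 14.8% to 17.7%). Only 8.43% overlapped H3K9me3, below the 18.3% expected (16.3% to 20.6%), and 11.8% overlapped H4K20me3 (5.69% expected, 4.81% to 6.58%). The MINA intervals left in KO overlapped H3K4me3 in 82.8% of cases (7.05% expected, 6.06% to 8.36%) and H3K36me3 in 58.8% (14.4% expected, 12.7% to 16.4%). Overlap with H3K9me3 was 5.98% (15.4% expected, 13.3% to 17.8%) and with H4K20me3 32.7% (10.1% expected, 8.81% to 12.1%). WT MINA intervals that were kept in KO lay on WT H3K4me3 in 94.0% of cases and those that were lost in 57.5%. The 1327 KO-only MINA intervals lay on KO H3K4me3 in 34.9% of cases. For the lost ones, which were not found in cells without mdig, the overlap was 35.5% with H3K36me3, 10.2% with H3K9me3 and 12.5% with H4K20me3 of WT cells. The lost intervals had a median width of 5.2 kb, against 4.0 kb for the kept ones. No expectation from shifts was computed for the kept, lost and KO-only intervals.

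By number, intervals that differed between the genotypes lay on WT MINA intervals less often than those that were kept. For H3K4me3 the shares were 63.5% of kept, 18.3% of WT-only and 10.3% of KO-only intervals. For H3K36me3 they were 36.4%, 7.15% and 19.6%, for H3K9me3 3.34%, 2.04% and 1.14%, and for H4K20me3 26.8%, 13.4% and 15.0%. Kept intervals were wider for all 4 marks, which raises the chance of an overlap (median widths of 6.0 kb for H3K4me3 and 13.4 kb for H3K36me3, against 2.0 and 5.6 kb for WT-only ones). By covered length, 15.6% of the KO-only H3K36me3 lay on WT MINA, against 15.02% of the kept part, while the other WT-only and KO-only parts of the 4 marks stayed below the kept ones.

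The heterochromatin marks were compared with each other, since H4K20me3 is laid down on chromatin that carries H3K9me3. In WT 65.1% of the H4K20me3 intervals overlapped H3K9me3 (19.3% expected, 17.4% to 21.7%) and in KO 68.5% (16.1% expected, 13.6% to 19.3%). Seen from H3K9me3, 11.6% of WT intervals overlapped H4K20me3 (4.01% expected, 3.43% to 4.61%) and 25.8% of KO intervals (8.13% expected, 6.92% to 10.3%). The length with both marks was 34.7 Mb in WT and 90.8 Mb in KO. Of the 118.9 Mb with H4K20me3 in KO only, 55.4% already carried H3K9me3 in WT. Over the H3K9me3 length found in both genotypes, H4K20me3 covered 14.4% in WT and 47.6% in KO. Part of the H4K20me3 intervals met H3K4me3. WT H3K4me3 was overlapped by 29.9% of kept, 16.2% of WT-only and 17.3% of KO-only H4K20me3 intervals. For H3K9me3 these shares were 3.01%, 1.47% and 1.72%. No expectation from shifts was computed for them. At promoters and gene bodies, 39.3% of H3K4me3 intervals overlapped H3K36me3 in WT (14.5% expected, 13.7% to 15.4%) and 44.6% in KO (14.3% expected, 13.0% to 15.3%).

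The KO over WT ratio of covered length was then compared between chromosomes. Chromosome X was chosen for this before the data were examined, from prior knowledge of the study and not from its labels, so it is not independent evidence. For H3K9me3 chromosome X stood outside the range of the 22 autosomes. It held 1.64 Mb in WT and 18.5 Mb in KO, a ratio of 11.3, where the autosomes ran from 0.554 on chromosome 12 to 2.30 on chromosome 18. The other extremes were 2.06 on chromosome 21, and 0.720 and 0.826 on chromosomes 17 and 1. Chromosome 19, rich in KRAB zinc finger genes that carry this mark, had 17.0 Mb in WT and 15.6 Mb in KO. For the other antibodies X lay within the range of the autosomes. H4K20me3 covered 9.40 times its WT length on X, below 12.5 on chromosome 15 and above 6.95 on chromosome 9, and the lowest ratios were on chromosomes 3 (0.881), 12 and 11 (1.33), where the ratios of interval number were 1.43 on chromosome 3 and 2.20 on chromosome 11. For H3K36me3 X had a ratio of 1.15, after 1.43 on chromosome 15 and 1.22 on chromosome 9, and chromosomes 3, 11 and 2 were lowest at 0.890, 0.895 and 0.906. For H3K4me3 chromosomes 15, 9 and 7 were highest at 1.14, 0.990 and 0.952, X had 0.910, and chromosomes 11, 3 and 10 were lowest at 0.770, 0.778 and 0.779. For MINA chromosomes 15, 9 and 6 were highest at 1.54, 0.768 and 0.682, X had 0.496, and chromosomes 22, 21 and 10 were lowest at 0.118, 0.143 and 0.153. Outside the raised stretches described next, the ratios of MINA on chromosomes 9 and 6 were 0.205 and 0.282 and that of H4K20me3 on chromosome 9 was 1.55. There the ratio of H3K36me3 was 0.741 on chromosome 9 and 0.902 on X, the ratios on X were 6.04 for H3K9me3 and 4.62 for H4K20me3, and those of H3K4me3 on chromosomes 9 and 7 were 0.745 and 0.715. Chromosomes 15 and 9 were thus among the 3 highest for each antibody except H3K9me3.

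**Figure D2:**
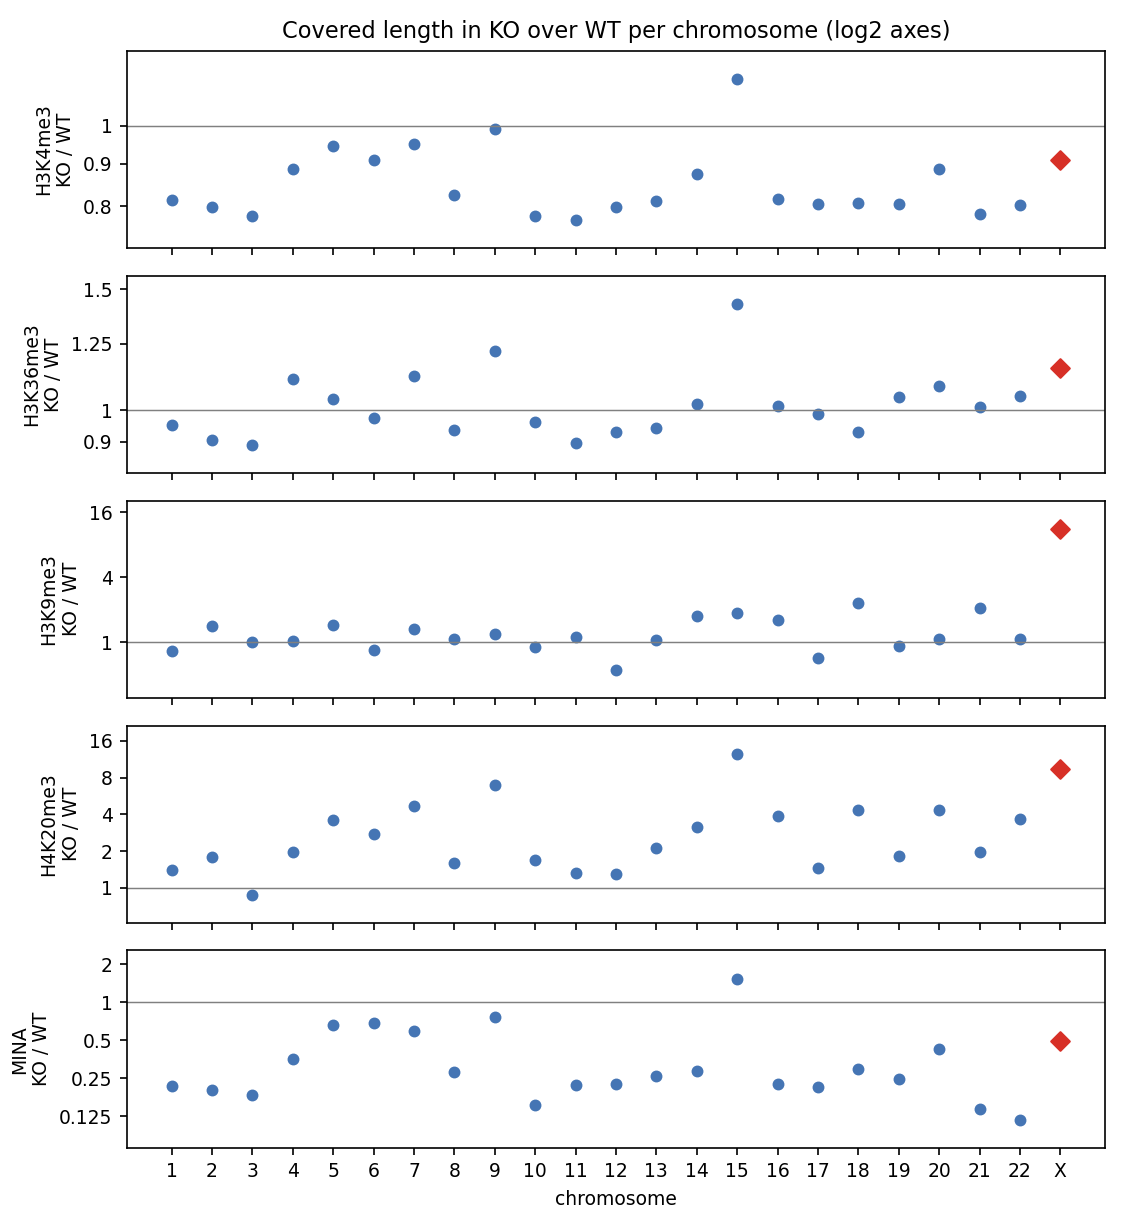
Covered length in KO divided by that in WT (vertical axes, log2 scale, 1 panel per antibody) for each chromosome (horizontal axis), with autosomes as circles and chromosome X as a diamond. Chromosome X has a ratio of 11.3 for H3K9me3, and chromosome 15 has the highest ratio for the other 4 antibodies.

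Along the chromosomes these ratios changed in long blocks that several antibodies shared. Cut from H3K4me3 alone, 11 raised stretches of 4.92 to 109.0 Mb on 8 chromosomes made up 698.2 Mb, or 23.0% of the span, and 45.8% of chromosome X. They were chosen after the profile had been seen. To the nearest 2-Mb bin they ran on chromosome 4 from 82000001, on chromosome 5 from 108000001 and on chromosome 9 from 34000001 to the last bin, on chromosome 6 from 24000001 to 66000000 and from 166000001 to the last bin, on chromosome 14 up to 62000000, and over all of chromosome 15. On chromosome 7 they ran up to 92000000 and again from 124000001. On chromosome X they ran from 52000001 to 66000000 and from 98000001 to the last bin. Most of the widest KO-only intervals named above lay in these stretches, and most of the WT-only ones lay outside. For H3K4me3 this follows in part from the definition of the stretches. The KO-only ones outside were on chromosome 10 for H3K4me3, 3 for H3K36me3, and 20 for H4K20me3 and MINA.

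Inside these stretches KO covered 1.04 times the WT length of H3K4me3, against 0.802 elsewhere. The other antibodies took no part in the cut. H3K36me3 had a ratio of 1.28 inside and 0.945 outside, MINA 0.935 inside and 0.225 outside, H4K20me3 8.77 inside and 1.68 outside, and H3K9me3 2.05 inside and 1.06 outside. In each of the 11 stretches H3K36me3, H4K20me3 and MINA were all above their ratio in the rest of the genome, while in 100 shifted placements of the stretches this held for 2.82 of them on average and 7 at most. H3K9me3 was above it in 9 of the 11. The rest of the genome for a shifted placement could still hold raised stretches, which made its bar higher. When the same model was run on H3K36me3 or on MINA alone, 94.2% and 91.7% of the 1529 bins fell in the same state as for H3K4me3. For H4K20me3 it was 80.5% (kappa, the agreement beyond chance, 0.450), and 57.5% of the raised bins were called. For H3K9me3 it was 75.7%, with a kappa of 0.167, against 0.828 for H3K36me3.

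**Figure D3:**
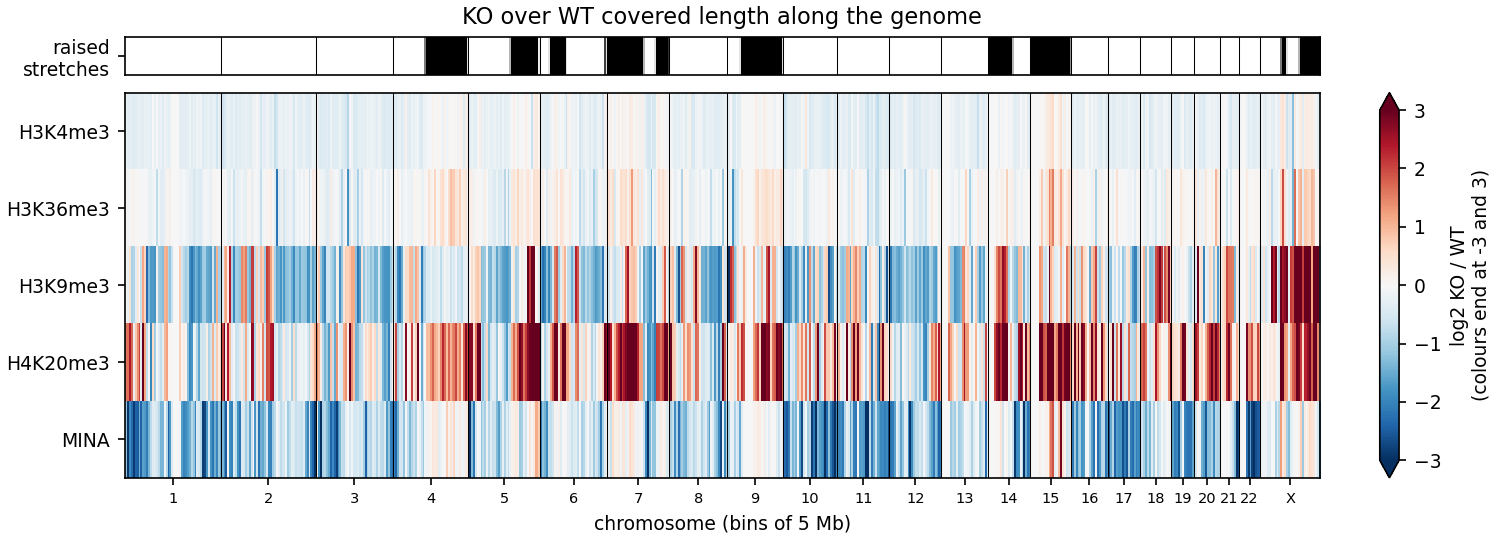
Log2 ratio of KO to WT covered length in bins of 5 Mb (20 kb added to each) along chromosomes 1 to 22 and X for the 5 antibodies, with the raised stretches as black bars above. H3K4me3, H3K36me3 and MINA turn lighter or red under the bars, while H3K9me3 has gains and losses of its own, the largest gains on chromosome X.

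The stretches bore on the comparison of chromosome X. In the 70.9 Mb of X inside them the H3K36me3 ratio was 1.44, and in the other 84.0 Mb it was 0.902, close to the 0.945 found outside the stretches in the whole genome. The MINA ratio on X was 0.581 inside and 0.310 outside, and that of H4K20me3 was 14.03 inside and 4.62 outside. The H3K9me3 ratio on X was 19.8 inside and 6.04 outside, so that KO was higher in both parts. In WT X held less H3K9me3 (1.64 Mb in 543 intervals) than any autosome. Its KO length of 18.5 Mb lay within the range of the autosomes, but its 5058 KO intervals were more than on any autosome (at most 4392, on chromosome 2). With X low in WT by both measures and high in KO by number only, a deficit in the WT list cannot be told apart from a gain in KO. The H4K20me3 ratio on X also started from few WT intervals (70 over 0.250 Mb), as did that on chromosome 15 (76 over 0.494 Mb). Chromosome 9 held 171 over 0.929 Mb. The drop of MINA in KO was uneven between the stretches and the rest, since 60.7% of the KO-only MINA length lay inside the stretches, against 6.74% of the WT-only length.

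**Figure D4:**
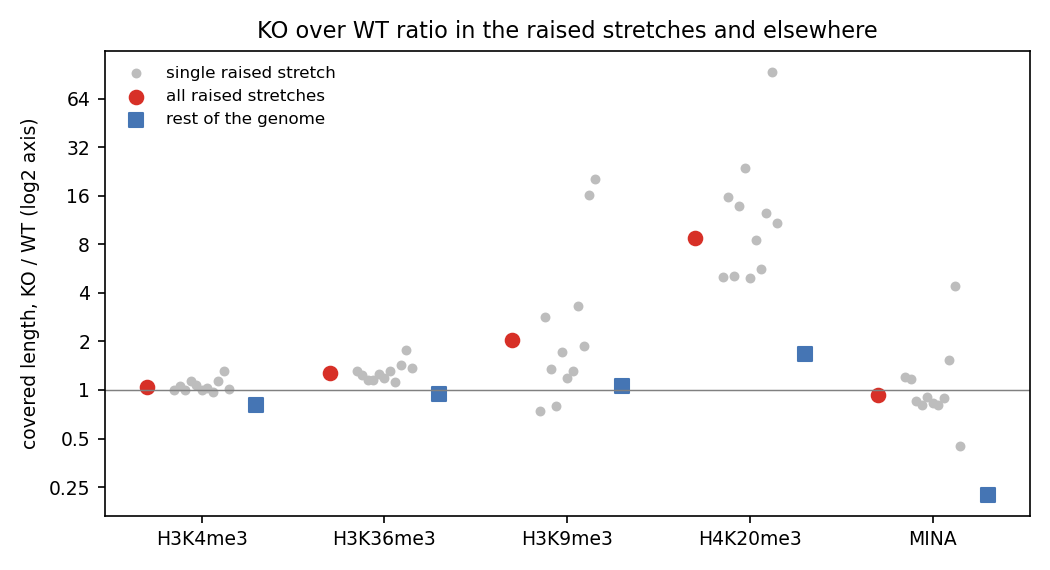
Covered length in KO divided by that in WT (vertical axis, log2 scale) for each antibody, in each of the 11 raised stretches (small grey points), in all of them together (circles) and in the rest of the genome (squares). The ratio is higher in the stretches for each antibody, from 1.04 against 0.802 for H3K4me3, which defined them, to 8.77 against 1.68 for H4K20me3.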

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

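The tests of explanations in this part were chosen after the results they bear on had been seen, while the overlap of MINA with H3K4me3, the shares of gained and kept H4K20me3 intervals on WT MINA and the share of KO MINA intervals found in WT come from comparisons fixed before the data were examined. Intervals on chromosome Y were outside the comparisons and drew attention because these lists held more than 3 of them, with 20 intervals for H3K9me3 in WT, 26 for H3K9me3 in KO and 18 for H4K20me3 in KO.

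In the raised stretches the MINA ratio was 4.16 times as high as outside. This does not decide on the depth or enrichment of whole libraries, since the length of called intervals need not move by 1 factor everywhere. On chromosomes without a raised stretch the MINA ratio ran from 0.118 on chromosome 22 to 0.297 on chromosome 18 and 0.423 on chromosome 20. Chromosome 20 also had the highest H3K4me3 ratio (0.886) and H3K36me3 ratio (1.08) of these chromosomes, so the cut may have missed a stretch there. A candidate explanation is that the WT and KO cells differ in the amount of DNA there, since H3K36me3, H4K20me3 and MINA were all above the rest of the genome in 11 of the 11 stretches defined from H3K4me3, beside 7 at most in shifted placements. These counts are not an even comparison, since shifted placements faced a higher bar. Nor is MINA independent of the cut, since 71.7% of its WT intervals lay on H3K4me3. H3K9me3, which a difference in DNA amount should raise too, was below its ratio outside (1.06) in 2 of the 11, with 0.738 on chromosome 4 and 0.798 at the end of chromosome 6. A chromatin change that follows mdig loss cannot be told apart from this, because genotype and culture coincide and less DNA in WT would also lower WT MINA calls there (10.4% of the WT MINA length lay in the stretches, which are 23.0% of the span). Read coverage of an input from each genotype would settle it, but the series holds 1 input, labelled with no genotype.

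The raised stretches as cut from H3K4me3 alone hold a large part of the wider H4K20me3 coverage in KO but not all of it. Inside them the covered length went from 5.17 Mb in WT to 45.3 Mb in KO. Outside them it went from 62.0 to 104.3 Mb, a KO over WT ratio of 1.68. That cut may miss some stretches. Outside it 12.6% of bins were raised when the model was run on H4K20me3 alone and 10.0% when run on MINA alone. A more sensitive KO library is not decided by the share of WT calls kept. Outside the stretches 43.6% of the WT length was kept and 53.3% of the WT intervals were found in KO. Without replicates it is unknown how much 2 libraries of the same cells would share. For H3K9me3, with a ratio of 1.06 outside the stretches, 59.7% of the WT length was kept there. Loss of mdig from the sites that gained the mark stays open, since 15.0% of the gained intervals lay on WT MINA intervals, against 26.8% of the kept ones, but these were wider and mdig below the calling threshold is not seen. Of the gained intervals 9.54% lay on KO MINA intervals, where the antibody gave signal without mdig. An indirect effect of mdig loss, and a difference between the cultures or immunoprecipitations, stay open and untested.

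For the MINA intervals in cells that lack mdig, background of the antibody at active promoters is a candidate source, since 82.8% of the KO intervals lay on H3K4me3, more than the 71.7% of the WT intervals, although 34.9% of the 1327 KO-only intervals did. The raised stretches do not account for them alone, as 5527 of the 7859 lay outside. Protein left in the KO cells cannot be told apart from background with these lists, because both predict that KO intervals recur in WT (83.1% did), and the labels state that the KO cells made none.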

How the results depend on the processing

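Without scores in the lists, the best-scoring 50% of intervals and equal numbers of best-scoring intervals were not run. The promoter, gene body and signal alternatives were not run for lack of gene positions and of values per interval, and no library could be left out with 1 per group. No paired analysis was possible because each group holds 1 library. Unknown depth limits each KO over WT ratio, since the length of a list moves with it. Adding chromosome Y left all 5 ratios of interval number within 1.5 times, and random placement left all 14 expected overlaps within the range of the shifts. The raised stretches kept their extent within 1.5 times with bins of 1 or 5 Mb or when taken from H3K36me3.

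Leaving out the raised stretches, requiring at least 2 kb, and the other bins were chosen after seeing the data. The values below differ from those of the report, and beyond the rule that defines each setting the cause was not tested. Of 57 results recomputed outside the raised stretches 17 stayed the same within counting error or 1.5 times, 36 moved and 4 changed direction. With 50% of the shorter interval 32 of 36 moved, with 50% of both 10 of 10, and with intervals of at least 2 kb 8 of 20. By interval number 26 of 32 chromosome ratios kept their direction and stayed within 1.5 times.

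With autosomes only, the H3K36me3 covered length ratio went from just above to just below 1 (1.00 in both). With intervals within 5 kb merged, the H3K9me3 number ratio was 0.771, below 1. By interval number the ratio passed 1 for H3K4me3 on chromosome 9 (1.02) and H4K20me3 on chromosome 3 (1.43). Outside the raised stretches the H3K36me3 ratios fell below 1 for interval number (0.978), covered length (0.945), chromosome X (0.902) and chromosome 9 (0.741). There the ratios on X were 6.04 for H3K9me3, 4.62 for H4K20me3 and 0.310 for MINA, in the same direction as on all of X. The ratios on chromosome 9 were 1.55 for H4K20me3 and 0.205 for MINA, and that of MINA on chromosome 6 was 0.282. By interval number the MINA ratios on chromosomes 22, 21 and 10 were 0.259, 0.307 and 0.325, and that of H4K20me3 on chromosome 11 was 2.20.

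Shares found in the other genotype are given as WT in KO, then KO in WT. With 50% of the shorter interval they were 84.4% and 84.4% for H3K36me3, 67.5% and 51.3% for H3K9me3, 53.3% and 18.7% for H4K20me3, and 37.6% and 81.7% for MINA. With 50% of both they were 79.0% and 85.2% for H3K4me3, 60.4% and 59.4% for H3K36me3, 35.4% and 30.4% for H3K9me3, 32.5% and 10.97% for H4K20me3, and 23.0% and 47.8% for MINA. Outside the stretches they were 83.6% and 95.7% for H3K4me3, 83.1% and 90.3% for H3K36me3, 66.8% and 57.8% for H3K9me3, 53.3% and 24.9% for H4K20me3, and 34.5% and 91.4% for MINA. With intervals of at least 2 kb they were 86.4% and 95.04% for H3K4me3, 64.3% and 54.0% for H3K9me3, 53.1% and 21.1% for H4K20me3, and 31.3% and 78.5% for MINA.

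Overlaps between antibodies are given as WT, then KO. With 50% of the shorter interval MINA overlapped H3K4me3 in 68.5% and 81.3%, H3K36me3 in 32.8% and 42.4%, H3K9me3 in 5.44% and 4.22%, and H4K20me3 in 9.83% and 30.6%. H4K20me3 overlapped H3K9me3 in 63.2% and 67.9%, H3K9me3 overlapped H4K20me3 in 11.2% and 25.4%, and H3K4me3 overlapped H3K36me3 in 24.9% and 31.3%. Outside the stretches MINA overlapped H3K4me3 in 69.9% and 87.1%, H3K9me3 in 9.14% and 5.30%, H4K20me3 in 12.9% and 28.0%, and H3K36me3 in 61.5% in KO. H3K9me3 overlapped H4K20me3 in 12.5% and 23.8%, H4K20me3 overlapped H3K9me3 in 70.1% in KO, and H3K4me3 overlapped H3K36me3 in 40.7% in WT.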

Other observations

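All tests in this part were chosen after the results they bear on had been seen. The 2 heterochromatin marks were compared by their joint state in WT and KO. Of the 220.0 Mb with H3K9me3 alone in WT, 35.7% carried neither mark in KO, 34.3% kept H3K9me3 alone and 26.1% carried both. Of the 32.5 Mb with H4K20me3 alone, 65.1% carried neither mark in KO and 30.8% kept it. Of the length without either mark in WT, 133.2 Mb had H3K9me3 alone in KO, 37.2 Mb had H4K20me3 alone and 15.8 Mb had both.

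H3K9me3 was also compared along the chromosomes. Among 442 bins of 5 Mb outside the raised stretches with at least 100 kb of the mark in WT and KO together, 56 were at least 2-fold higher in KO and 194 at least 2-fold lower. Over all 576 such bins the counts were 99 and 201. The 5 largest losses, chosen by this ranking after the values were seen, included chromosome 9 from 1 to 5000000 (0.674 Mb in WT, 0.0592 Mb in KO) and chromosome 10 from 115000001 to 120000000 (0.522 and 0.0658 Mb). Of the 5 largest gains 4 lay on chromosome X, led by 90000001 to 95000000 (0.0070 Mb in WT, 1.42 Mb in KO), and the other on chromosome 20 from 5000001 to 10000000 (0.103 and 1.59 Mb). In these bins on X H3K36me3 covered little in either genotype.

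Whether both heterochromatin marks followed one program was asked across these bins, which are not independent replicates. Outside the raised stretches the log2 ratios of H3K9me3 and H4K20me3 had a Spearman correlation of 0.70 over 432 bins, while the other 9 pairs of antibodies ran from -0.32 for H3K36me3 and MINA to 0.40 for H3K36me3 and H4K20me3. A shared change in heterochromatin, a shared property of the cultures, or H3K9me3 material in the KO H4K20me3 library may lie behind it. Whether H3K9me3 was gained where active chromatin was sparse stays open. The Spearman correlation between its log2 ratio and WT H3K36me3 was negative and weak (-0.22 outside the stretches, -0.29 over all bins), and the median WT H3K36me3 length was 0.297 Mb in bins at least 2-fold higher and 0.561 Mb in those at least 2-fold lower.

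The KO H4K20me3 list had a higher Jaccard index with the H3K9me3 lists (0.268 with WT and 0.249 with KO) than with the WT H4K20me3 list (0.165). This index depends on list length, and the WT H4K20me3 list covered 67.2 Mb, against 254.7 and 305.7 Mb for H3K9me3. The KO H4K20me3 list covered 45.7% of the WT H4K20me3 length and 29.7% of the KO H3K9me3 length. The index alone therefore does not show whether that library holds H3K9me3 material. Among KO H3K9me3 intervals of 10 to 20 kb those found in KO only lay on KO H4K20me3 in 28.3% of 861 cases (95% Wilson interval 25.4% to 31.4%) and those also found in WT in 62.8% of 3289 (61.1% to 64.4%). This does not decide it, since intervals found in both genotypes are expected to be the stronger ones, a small share of H3K9me3 material would also be called there more often, and the lists hold no heights.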
